A study of Pan troglodytes with 8 samples.

How the data were processed

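Chromatin accessibility was measured by bulk ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in cells sorted from chimpanzee cerebral organoids. Per the labels' protocols, the organoids were grown from the induced pluripotent stem cell line SandraA, starting from 9000 cells per well, and were collected in week 8 of culture, within 3 days either way. Flow cytometry gave 4 populations: BCL11B-positive neurons (N), intermediate progenitors of the basal kind (bIP), and radial glia of the basal (bRG) and apical (aRG) kinds. Per the labels' protocols, transposition lasted 2 hours, crosslinks were reversed at 65 °C overnight as for fixed cells, and fragments of 150 to 1000 bp were kept. Each of the 4 populations had 2 libraries, 8 in all. The labels do not say whether the libraries numbered 1 and 2 came from separate cultures, so the p-values measure the spread between these samples only.

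The deposited table held whole-number read counts per region for the 8 libraries, unscaled, with the region's identifiers in human, chimpanzee and gorilla coordinates and the closest gene and its distance, per the file headers. The submitters' processing notes list bcl2fastq 2.20.0, MACS2 and the genome builds panTro6 and hg38, without saying which step used each. The aligner, the way in which regions of the 3 species were matched, and the source of the closest genes are not given in the sources used here. One deposited consensus peak list per population gave, per the file headers and the narrowPeak layout, a display score, a fold enrichment over local background (a ratio), a -log10 p-value and a -log10 q-value for each peak. How the 2 libraries of a population were combined into its list is not given in the sources used here. Of these columns only the intervals and the -log10 q-value were used, since fold enrichments and scores from separately called peaks are not comparable between populations.

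The table held 218080 regions, of which 6725 had no chimpanzee identifier and a total count of 0. After removal of these and of 7 repeated chimpanzee identifiers, 211348 regions remained, with a median width of 858 bp and 5th and 95th percentiles of 340 and 1832 bp. All coordinates are chimpanzee panTro6, printed from 1. Region starts equalled 54881 starts in the peak lists when read as counted from 0 and 11 when read as counted from 1, so 1 was added to each start. Regions with identifiers in all 3 species numbered 198933, and 2123 had a chimpanzee identifier only. No region lay on human chromosome X or Y, so DCX, a neuronal gene on X, was not measured. The distances pointed to 1 position per gene in 99.5% of 58292 regions tested, and are treated as distances to gene starts. They are measured from the region's edge and have no sign. Their build is not stated, and this test used human hg38 coordinates, so distances printed beside chimpanzee coordinates are not known to be chimpanzee ones.

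The table named 41376 closest genes, of which 14256 matched a protein-coding symbol in a table of gene names of assembly NHGRI_mPanTro3-v2.0, used for names only. A gene locus was defined as the sum of counts over regions whose closest gene was that protein-coding gene, at most 50 kb away. This assigned 47822 regions to 14234 genes. A locus stands for nearness to a gene start, not for regulation of that gene. The plan had been to take the nearest protein-coding start. The table instead gives the closest gene of any type, so regions nearest to a non-coding gene or pseudogene were left out of the loci.

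Differences were tested with edgeR 4.0.16 (quasi-likelihood F-test, robust fit, TMM scaling, filterByExpr) in 1 fit of all 8 libraries with population as the only term. The filter kept 198227 regions and removed 13121, and 14117 gene loci were tested. The fit had 4 residual and 8.62 prior degrees of freedom and a common biological coefficient of variation of 0.216. All 6 pairs of populations were compared, and differences among the 4 populations were tested jointly. A region or locus was called at a Benjamini-Hochberg adjusted p under 0.05. "Rose" and "fell" are used for items past this threshold. CPM values use library totals scaled by TMM, and log2 values carry a prior count of 2. Totals per library lay between 24913928 and 34845193 counts. Intervals for shares of single peak lists are 95% Wilson intervals. Intervals and floors of 3 counts cover counting error only.

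Lists of marker and pathway genes, 30 lists of 534 genes in all, were fixed before the data were examined, as were the comparisons, the tests and most of the other settings tried. Each list was compared with all other loci by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over 180 tests of 30 lists and 6 comparisons. The same test with a correlation estimated from the libraries was run beside it. None of the 83 list tests past the threshold passed with the estimated correlation. Calls of list members are given over all loci tested and adjusted over the list alone. Medians and means of lists are of log2 fold changes at loci. Lists are printed for comparisons with aRG and for N with bIP, not for bIP or N with bRG. Some genes belong to several lists, so the lists are not independent of each other.

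Genes and regions named singly were chosen by a rule fixed before the data were examined. Markers SOX2, PAX6, HOPX, EOMES, NEUROG2, BCL11B and TBR1 were always named. For each comparison with aRG and for N with bIP, the rule took the 10 largest rises and 10 largest falls among called loci of at least 10 CPM over at least 2 regions that moved the same way in both pairs of same-numbered libraries. It also took up to 4 called members of each list with the largest change. Regions were the 3 largest rises and 3 largest falls of at least 1 CPM, under the same condition on pairs. The rule gave 419 gene-by-comparison results. For length, 145 of them were kept: the markers, the leading 3 rises and falls, and the leading 2 members of each list that passed the camera test. This narrowing was made after values had been seen, by rank alone. Of the items kept, 1 gene and 1 region are not reported here.

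The procedure was tested on simulated counts drawn from the means and library sizes of these samples, with 200 items changed by known factors between bRG and aRG. With no simulated change, between 0 and 3 regions or loci were called per comparison. Overlap of peak lists was computed with bedtools 2.31.1, on intervals after removing repeated entries that differed only in summit. Other software was R 4.3.3, data.table at version 1.17.8, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

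Alternatives were DESeq2's size factors (as RLE in edgeR), total counts, and a loess fit on abundance in place of TMM. Others were no filter on low counts, DESeq2 1.42.0 in place of edgeR, a replicate block, only the 4 libraries of a comparison, and leaving out each of the 8 libraries. For loci, a 10 kb window and regions within 1000 bp of a gene start were used in place of 50 kb. For peak lists, a reciprocal overlap of 50% and the most significant part of each list were tried. Motif shares and corrections for GC content were planned but not run. Libraries of different populations share the numbers 1 and 2, but the labels state no pairing or batch, so the libraries were not treated as pairs.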

Results

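Accessibility was compared between 4 cell populations of the developing cortex, sorted from chimpanzee cerebral organoids. Apical radial glia are the stem cells that line the ventricle, and basal radial glia are their relatives that have left it. Basal intermediate progenitors are shorter-lived dividing cells that mostly make neurons. The series concerns features of basal radial glia in the evolution of the human neocortex, and these libraries are its chimpanzee ATAC-seq part. Each population had 2 libraries. Library totals were 27883664 and 24994712 counts for aRG, 34845193 and 28970824 for bRG, 26083288 and 24913928 for bIP, and 31593644 and 25221705 for N.

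The radial glia resembled each other closely, and bIP lay between them and neurons. Across regions, the correlation of log2 CPM was 0.967 between the aRG libraries and 0.969 between the bRG libraries, and 0.962 to 0.975 between aRG and bRG libraries. It was 0.951 within bIP and 0.945 within N. Correlations between aRG and bIP were 0.731 to 0.805, between bIP and N 0.652 to 0.815, and between aRG and N 0.384 to 0.468. These correlations are across regions, which are not independent replicates. The leading principal component, with 77.9% of the variance, ran from aRG (-384.1 and -358.3) through bRG (-319.8 and -303.9) and bIP (176.3 and 63.9) to N (542.2 and 583.7).

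**Figure D1:**
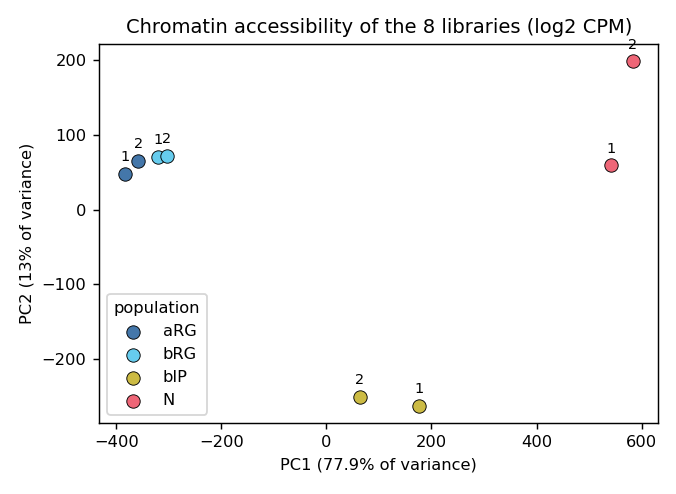
Principal components of log2 CPM over the tested regions, with 1 point per library, coloured by population and numbered by replicate. The aRG and bRG libraries lie together on the left, the N libraries on the right, and the bIP libraries apart from both on the vertical axis, which carries 13% of the variance.

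The deposited consensus peak lists showed the same order. They held 85863 intervals for aRG, 89358 for bRG, 84922 for bIP and 86389 for N, covering 73.7, 76.7, 72.7 and 73.3 Mb. Of the aRG intervals, 91.1% (95% Wilson interval 90.93 to 91.31) were overlapped by a bRG interval, 66.1% by a bIP interval and 50.4% by an N interval. Of the N intervals, 66.4% were overlapped in bIP and 50.4% in aRG. Intervals in no other list made up 5.8% of the aRG list, 7.3% of the bRG list, 12.3% of the bIP list and 29.8% (29.53 to 30.14) of the N list. There was 1 list per population, so these shares have no replicate spread.

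Most regions differed among the populations. In edgeR's joint quasi-likelihood test, 145604 of 198227 regions (73.5%) passed the threshold. Pairwise counts were largest for N against aRG, at 136707 regions (69%), and for N against bRG, at 134570 (67.9%). They were 94351 (47.6%) for N against bIP, 93512 (47.2%) for bIP against aRG and 84950 (42.9%) for bIP against bRG. The count for bIP against bRG fell to 56230 without bIP 1. At gene loci, 7466 of 14117 (52.9%) differed between N and aRG, 4414 (31.3%) between bIP and aRG, and 4124 (29.2%) between N and bIP. The locus counts for bIP against aRG were 2500 without aRG 1, 2887 without aRG 2 and 2599 without bIP 1, and those for N against bIP were 2406 without N 2 and 2430 without bIP 2.

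**Figure D2:**
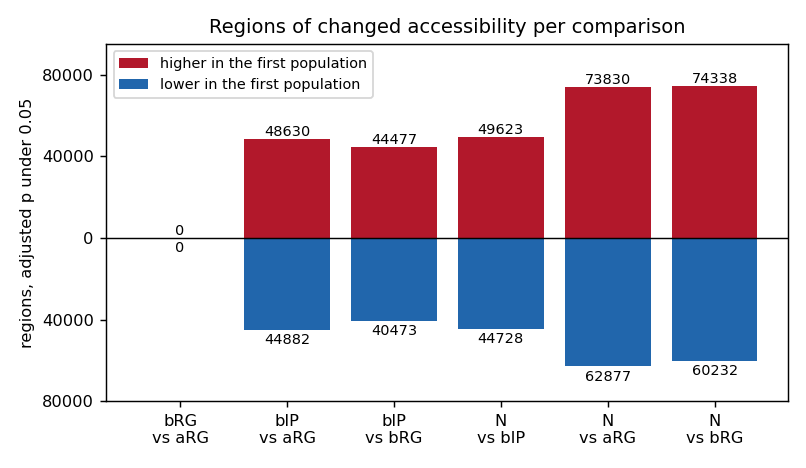
Numbers of regions with an adjusted p under 0.05 in edgeR for the 6 pairs of populations, with bars upward for regions higher in the population named first and downward for regions lower in it. No region passed for bRG against aRG. The counts were 73830 higher and 62877 lower for N against aRG, and 74338 higher and 60232 lower for N against bRG.

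Marker genes of these cell types were examined at their loci. SOX2, a transcription factor that keeps neural stem cells undifferentiated, had 258 ± 27.3 CPM in aRG, 251 ± 6.45 in bRG, 138 ± 12.8 in bIP and 51.7 ± 6.12 in N (SD, n = 2 throughout), over 4 regions. PAX6, which specifies cortical radial glia, had 121 ± 16.3, 129 ± 4.78, 86.4 ± 5.55 and 51.1 ± 3.1 CPM in the same order. HOPX, whose transcript marks basal radial glia in primate cortex, had 223 ± 20.8 CPM in aRG and 218 ± 6.63 in bRG, then 142 ± 2.09 in bIP and 57.6 ± 8.09 in N. EOMES, the defining transcription factor of intermediate progenitors, had 128 ± 2.35 CPM in aRG, 115 ± 15.3 in bRG, 211 ± 3.31 in bIP and 103 ± 27.4 in N. TBR1, a factor of early cortical neurons, had 76.1 ± 8.46, 67.9 ± 0.135, 190 ± 18.6 and 127 ± 7.6 CPM. BCL11B, by which the neurons are labelled, had 146 ± 12, 144 ± 12.3, 185 ± 8.83 and 123 ± 12.6 CPM. NEUROG2, which starts neurogenesis, was represented by 1 region with 16.3 ± 7.36, 18 ± 7.15, 7.86 ± 1.86 and 3.45 ± 1.09 CPM.

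**Figure D3:**
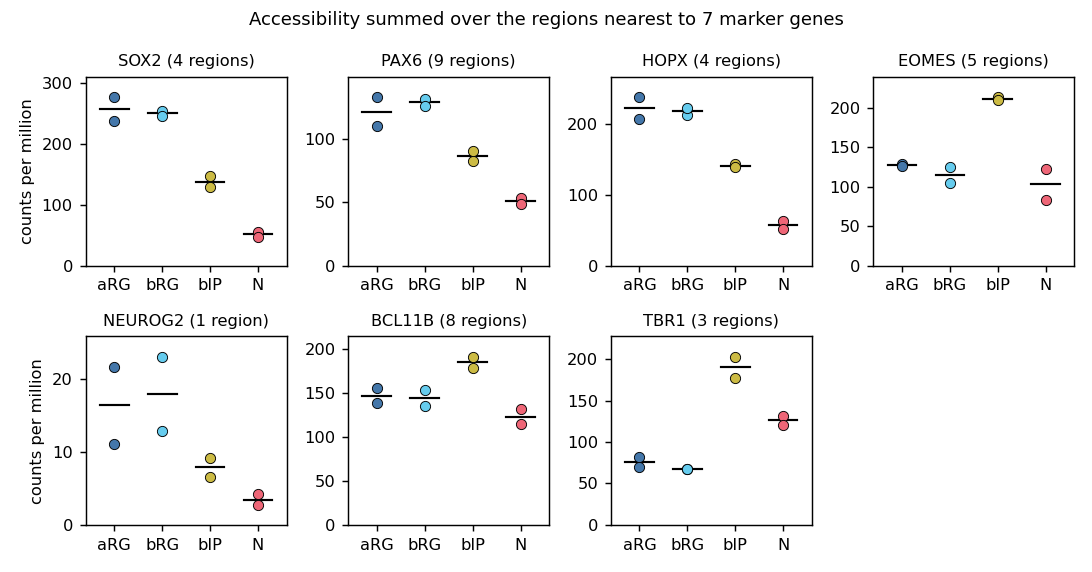
Locus CPM of 7 marker genes, with 1 point per library and a bar at the mean of the 2 libraries of each population. SOX2, PAX6 and HOPX lie highest in aRG and bRG and lowest in N, while EOMES, TBR1 and BCL11B lie highest in bIP.

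The comparison of bRG with aRG asks what sets the basal stem cells apart from those at the ventricle. No difference was called. The marker loci of radial glia had close values in both. Log2 fold changes with SE were -0.04 ± 0.11 at SOX2, 0.09 ± 0.1 at PAX6 and -0.03 ± 0.1 at HOPX. They were -0.16 ± 0.16 at EOMES, 0.13 ± 0.39 at NEUROG2, -0.02 ± 0.1 at BCL11B and -0.16 ± 0.1 at TBR1, each with adjusted p = 1 in edgeR. Of 198227 regions, 0 passed edgeR's test, 5232 had an unadjusted p under 0.05 where 9911 would be expected by chance, and DESeq2 called 0, with 2331 unadjusted. Of 14117 loci, 0 passed in edgeR (127 unadjusted) and 0 in DESeq2 (73 unadjusted). Same-numbered aRG and bRG libraries varied together (correlation 0.31), which the fit does not model. With a replicate block, 8802 regions and 385 loci had an unadjusted p under 0.05, and again 0 passed. All these counts lie below chance, so the tests were too strict for this pair. With 200 changes simulated without such pairing, the fit without a block recovered 2 of 67 regions changed 2-fold and 27 of 66 changed 4-fold. For loci it recovered 37 of 67 changed 1.5-fold and 65 of 66 changed 4-fold. Lacking the pairing, these rates do not measure power here. A block or more changed regions were not simulated.

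Gene lists moved little between bRG and aRG, and 0 members were called in any list, also when adjusted over the list alone. The morphoregulatory and protrusion list, on the cell-shape genes that the series title names, had a median of -0.04 over 23 loci, a mean of 0.02 and a downward camera test (adjusted p = 0.17, and adjusted p = 0.42 with an estimated correlation). The basal radial glia list had a median of 0.02 over 18 loci (camera adjusted p = 0.05, under the threshold before rounding, and adjusted p = 0.49 with an estimated correlation). That call ended without aRG 2 (0.76), without bRG 2 (0.47) and with a 10 kb window (0.45), within a range of 0.0046 to 0.76 over 14 settings. Lists with a camera call were lower for inhibitory neuron and ganglionic eminence genes (median -0.08 over 17 loci, adjusted p = 0.0057, and adjusted p = 0.43 with an estimated correlation), and for cell cycle genes (-0.05 over 24, adjusted p = 0.012, and adjusted p = 0.56 with an estimated correlation). They were also lower for choroid plexus and hem genes (-0.07 over 16, adjusted p = 0.024, and adjusted p = 0.42 with an estimated correlation) and axon guidance genes (-0.05 over 24, adjusted p = 0.036, and adjusted p = 0.42 with an estimated correlation). Pluripotency genes were higher (0.11 over 9, adjusted p = 0.034, and adjusted p = 0.42 with an estimated correlation).

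Each of these calls ended when some single library was left out. The inhibitory list gave 0.79 without aRG 1 and 0.056 without bRG 2 (0.0001 to 0.79 over 14 settings). The cell cycle list gave 0.63 without aRG 2, and 0.53 with the direction reversed without bRG 1 (1.4e-07 to 0.63). The choroid plexus list gave 0.12 without aRG 2, 0.33 without bRG 2 and 0.075 with a 10 kb window (0.011 to 0.33). The axon guidance list gave 0.98 with the direction reversed without aRG 1, 0.1 without bRG 1, 0.12 without bRG 2 and 0.11 with loess scaling (0.0015 to 0.98). The pluripotency list gave 0.08 without aRG 1, 0.17 without aRG 2, 0.28 without bRG 1, 0.11 with a 10 kb window and 0.091 with loess scaling (0.027 to 0.28). These values are camera adjusted p.

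The comparison of bIP with aRG sets neuron-making progenitors against stem cells. Many loci of radial glia genes were lower in bIP, and many loci of progenitor and pan-neuronal genes were higher. Among markers, SOX2 (-0.90 ± 0.11, adjusted p = 0.00063), PAX6 (-0.49 ± 0.10, adjusted p = 0.0085) and HOPX (-0.65 ± 0.10, adjusted p = 0.002) fell, and EOMES (0.72 ± 0.16, adjusted p = 0.0097), TBR1 (1.32 ± 0.10, adjusted p = 0.00013) and BCL11B (0.34 ± 0.10, adjusted p = 0.035) rose, given as log2 fold change ± SE by edgeR's quasi-likelihood test. NEUROG2 (-1.05 ± 0.41, adjusted p = 0.087) did not pass, but did with DESeq2 (adjusted p = 0.044) and with a replicate block (0.027), within a range up to 0.47. PAX6 lost its call without aRG 1 (-0.34), without bIP 1 (-0.43) and at regions near the gene start alone (-0.22), with adjusted p up to 0.29. EOMES lost its call without aRG 1 (0.74) or aRG 2 (0.71), with adjusted p up to 0.059. BCL11B lost it without aRG 1 (0.42), aRG 2 (0.26), bIP 1 (0.28) or bIP 2 (0.38), with adjusted p up to 0.2. In total 48630 regions rose and 44882 fell (29402 without bIP 1), and 2343 loci rose and 2071 fell (921 and 996 near gene starts).

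The basal intermediate progenitor, pan-neuronal, synapse and Cajal-Retzius lists rose from aRG to bIP. Neuronal lists by cortical layer did not pass and had medians below 0, both for deep-layer neurons (3 rose and 6 fell of 15, 3 and 7 adjusted over the list alone, median -0.25, camera adjusted p = 0.29, and adjusted p = 0.61 with an estimated correlation) and for upper-layer neurons (3 rose and 4 fell of 13, 3 and 6 adjusted over the list alone, median -0.29, camera adjusted p = 0.35, and adjusted p = 0.67 with an estimated correlation). Of the 21 measured loci of the basal intermediate progenitor list, 14 rose, 0 fell and 7 did not pass (15 and 1 adjusted over the list alone). Their median log2 fold change was 0.43 (camera adjusted p = 1.1e-07, and adjusted p = 0.42 with an estimated correlation). Its leading members were SSTR2 (2.87 ± 0.47, adjusted p = 0.0025), a somatostatin receptor of migrating neurons and progenitors, and SRRM4 (2.33 ± 0.13, adjusted p = 5.5e-05), a splicing regulator of neuronal exons. SSTR2 rose by 3.50 without aRG 2. Of 24 pan-neuronal loci, 14 rose, 1 fell and 9 did not pass (17 and 1 adjusted over the list alone). The median was 0.71 (camera adjusted p = 2.6e-11, and adjusted p = 0.14 with an estimated correlation). A leading member was NEUROD2 (2.59 ± 0.11, adjusted p = 3.4e-05), a transcription factor of newborn excitatory neurons. NEUROD2 went from 49.9 ± 6.05 CPM in aRG to 300 ± 36.8 in bIP and 380 ± 2.6 in N. Of 27 synapse and ion channel loci, 14 rose, 0 fell and 13 did not pass (14 and 0 adjusted over the list alone). Their median was 0.48 (camera adjusted p = 0.00023, and adjusted p = 0.42 with an estimated correlation). Among its leading members was GRIK2 (1.19 ± 0.30, adjusted p = 0.018), a kainate receptor gene. The GRIK2 call ended without aRG 1 (1.03), aRG 2 (1.36) or bIP 2 (0.95) and with DESeq2 (1.2), with adjusted p up to 0.13. Of 8 Cajal-Retzius loci, genes of the earliest marginal-zone neurons, 4 rose, 0 fell and 4 did not pass (4 and 0 adjusted over the list alone). The median was 0.62 (camera adjusted p = 0.014, and adjusted p = 0.47 with an estimated correlation). Its leading members were CACNA2D2 (1.71 ± 0.26, adjusted p = 0.0019), a calcium channel subunit, and CALB2 (1.70 ± 0.30, adjusted p = 0.0037), a calcium-binding protein. CACNA2D2 lost its call with a 10 kb window (0.37) and near the gene start (0.40), with adjusted p up to 0.16.

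Lists of radial glia genes fell from aRG to bIP. Of 21 shared radial glia loci, 0 rose, 12 fell and 9 did not pass (0 and 14 adjusted over the list alone). Their median was -0.49 (camera adjusted p = 5.1e-06, and adjusted p = 0.42 with an estimated correlation). FABP7, a fatty-acid carrier of the radial fibre, and HES1, the Notch effector that holds progenitors undifferentiated, led the falls with FABP7 (-1.15 ± 0.17, adjusted p = 0.0018) and HES1 (-1.11 ± 0.14, adjusted p = 0.00085). HES1 went from 180 ± 4 CPM in aRG to 83.3 ± 19.9 in bIP and 34.8 ± 3.98 in N. Of 18 basal radial glia loci, 0 rose, 11 fell and 7 did not pass (0 and 11 adjusted over the list alone). The median was -0.52 (camera adjusted p = 1.7e-05, and adjusted p = 0.42 with an estimated correlation). They were led by SLCO1C1 (-1.77 ± 0.18, adjusted p = 0.00032), a thyroid hormone transporter, and ITGB5 (-1.71 ± 0.14, adjusted p = 0.00016), an integrin subunit. Of 15 glial loci, 0 rose, 4 fell and 11 did not pass (0 and 4 adjusted over the list alone). Their median was -0.39 (camera adjusted p = 0.02, and adjusted p = 0.42 with an estimated correlation). SPARCL1 and GJA1, astrocyte genes that radial glia also express, led them with SPARCL1 (-1.65 ± 0.11, adjusted p = 7.2e-05) and GJA1 (-1.26 ± 0.16, adjusted p = 8e-04). The glial call ended without bIP 2 (0.076, range 0.0058 to 0.076). Of 24 cell cycle loci, 2 rose, 9 fell and 13 did not pass (2 and 9 adjusted over the list alone). The median was -0.21 (camera adjusted p = 0.017, and adjusted p = 0.58 with an estimated correlation). The mitotic kinase AURKB (-0.84 ± 0.20, adjusted p = 0.012) and the nucleotide-making enzyme RRM2 (-0.82 ± 0.13, adjusted p = 0.0021) led them. The list's call ended without aRG 2 (0.058, range 0.00088 to 0.058), and that of AURKB without aRG 2 (-0.77) or bIP 1 (-0.68), with adjusted p up to 0.082. Apical radial glia genes (1 rose and 4 fell of 13, median -0.21) did not pass the camera test (adjusted p = 0.12, and adjusted p = 0.43 with an estimated correlation).

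Most signalling lists and the matrix list also fell from aRG to bIP. The Notch list did not pass (5 rose and 5 fell of 21, 5 and 6 adjusted over the list alone, median -0.09, camera adjusted p = 0.78, and adjusted p = 0.9 with an estimated correlation), and its mean was 0.03. Of 21 BMP and TGF-beta loci, 1 rose, 11 fell and 9 did not pass (1 and 13 adjusted over the list alone), led by the receptors BMPR2 (-1.47 ± 0.20, adjusted p = 0.0011) and TGFBR2 (-1.27 ± 0.16, adjusted p = 0.00071). Their median was -0.47 (camera adjusted p = 1.7e-05, and adjusted p = 0.42 with an estimated correlation). Of 15 FGF loci, 0 rose, 10 fell and 5 did not pass (0 and 10 adjusted over the list alone), led by ETV4 (-0.97 ± 0.11, adjusted p = 0.00041), a target of FGF signalling, and the receptor FGFR2 (-0.82 ± 0.12, adjusted p = 0.0013). The median was -0.35 (camera adjusted p = 0.00044, and adjusted p = 0.42 with an estimated correlation). Of 21 extracellular matrix and integrin loci, 2 rose, 13 fell and 6 did not pass (2 and 13 adjusted over the list alone), where ITGB5 was followed by the collagen receptor subunit ITGA2 (-0.99 ± 0.13, adjusted p = 0.00085). Their median was -0.45 (camera adjusted p = 8.7e-05, and adjusted p = 0.27 with an estimated correlation). Of 12 Hippo loci, 0 rose, 4 fell and 8 did not pass (0 and 5 adjusted over the list alone). The median was -0.43 (camera adjusted p = 0.014, and adjusted p = 0.42 with an estimated correlation). Its leading members were the receptor kinase AXL (-1.02 ± 0.23, adjusted p = 0.0095) and the matricellular target gene CCN1 (-0.88 ± 0.12, adjusted p = 0.0011), and AXL lost its call without aRG 1 (-0.99) or bIP 1 (-0.92), with adjusted p up to 0.064. Of 12 Hedgehog loci, 2 rose, 7 fell and 3 did not pass (2 and 9 adjusted over the list alone), led by GLI3 (-0.70 ± 0.10, adjusted p = 0.0016), which patterns the dorsal telencephalon, and the signal transducer SMO (-0.57 ± 0.08, adjusted p = 0.0016). Their median was -0.39 (camera adjusted p = 0.033, and adjusted p = 0.42 with an estimated correlation). That list call ended without aRG 1 (0.06, range 0.022 to 0.06). Of 27 Wnt loci, 2 rose, 9 fell and 16 did not pass (2 and 10 adjusted over the list alone). The median was -0.21 (camera adjusted p = 0.016, and adjusted p = 0.53 with an estimated correlation). The ligand gene WNT5A (2.92 ± 0.35, adjusted p = 0.00055) went against the list, with 2.33 without bIP 1, while WNT3A (-1.08 ± 0.27, adjusted p = 0.016), a ligand of the cortical hem, fell. WNT3A lost its call without aRG 1 (-0.92), without bIP 2 (-0.89) and with a 10 kb window (-0.13), with adjusted p up to 0.8. The Wnt list lost its call without bIP 2 (0.063) and with a 10 kb window (0.083, range 0.0059 to 0.083).

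A pair of lists for cells outside the cortical lineage also passed. Of 10 endothelial and immune loci, 6 rose, 1 fell and 3 did not pass (6 and 1 adjusted over the list alone). Their median was 1.38 (camera adjusted p = 0.00032, and adjusted p = 0.42 with an estimated correlation). The loci of FLT1 (3.36 ± 0.29, adjusted p = 0.00017), a vascular growth factor receptor, and C1QA (3.07 ± 0.29, adjusted p = 0.00023), a microglial complement gene, led them, and FLT1 went from 6.87 ± 0.713 CPM in aRG to 70.6 ± 13 in bIP. With a 10 kb window the list did not pass (0.13, range 0.00022 to 0.13). Of 18 mesenchyme and neural crest loci, 0 rose, 6 fell and 12 did not pass (0 and 6 adjusted over the list alone). The median was -0.38 (camera adjusted p = 0.029, and adjusted p = 0.42 with an estimated correlation). That call ended without aRG 1 (0.079) or bIP 2 (0.076, range 0.014 to 0.079). Its leading members were the transcription factor genes TWIST2 (-1.14 ± 0.34, adjusted p = 0.032) and SNAI2 (-0.70 ± 0.13, adjusted p = 0.0037), and TWIST2 lost its call without aRG 1 (-1.06), aRG 2 (-1.22), bIP 1 (-1.43) or bIP 2 (-0.90), with adjusted p up to 0.15. The morphoregulatory list (1 rose and 4 fell of 23, also adjusted over the list alone, median -0.01) did not pass (camera adjusted p = 0.34, and adjusted p = 0.49 with an estimated correlation).

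The largest rises from aRG to bIP were at KRTAP12-3 (4.02 ± 0.52, adjusted p = 0.00082), a hair keratin gene, NPPA (3.87 ± 0.20, adjusted p = 3.4e-05), a natriuretic peptide gene, and TPCN1 (3.79 ± 0.54, adjusted p = 0.0012), a lysosomal channel gene. Without bIP 1 the value for KRTAP12-3 was 3.37. NPPA had 5.45 ± 0.756 CPM in aRG and 79.9 ± 5.26 in bIP. The largest falls were at NMS (-2.63 ± 0.27, adjusted p = 0.00031), a neuropeptide gene, TRPM8 (-2.37 ± 0.24, adjusted p = 0.00029), a cold-sensing channel gene, and SSMEM1 (-2.36 ± 0.30, adjusted p = 0.00072), a little-studied membrane protein gene. SSMEM1 gave -0.52 with a 10 kb window, with adjusted p up to 0.35. Among single regions, 16:38062449-38063017 rose from 0.0616 ± 0.0317 to 3.07 ± 0.541 CPM (log2 fold change 5.56 ± 0.5, adjusted p = 9.5e-06). Next came 16:35694589-35695001 (5.54 ± 0.58, adjusted p = 2.2e-05) and 18:51216300-51216960 (5.37 ± 0.48, adjusted p = 9.1e-06). Among the leading falls were 17:22983192-22983588, 8587 bp from ASIC2 (-3.86 ± 0.68, adjusted p = 0.00058), and 10:5449690-5450454 (-3.83 ± 0.63, adjusted p = 0.00036).

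The comparison of N with aRG sets neurons against stem cells. Many loci of radial glia genes were lower in N, and many pan-neuronal and synaptic loci were higher. Among markers, SOX2 (-2.31 ± 0.12, adjusted p = 1.2e-05), HOPX (-1.95 ± 0.11, adjusted p = 1.2e-05), NEUROG2 (-2.22 ± 0.44, adjusted p = 0.0031) and PAX6 (-1.25 ± 0.11, adjusted p = 4.4e-05) fell and TBR1 (0.74 ± 0.10, adjusted p = 0.00046) rose, by edgeR's quasi-likelihood test. EOMES (-0.31 ± 0.16, adjusted p = 0.14) did not pass, but did without N 1 (-0.62, adjusted p = 0.0043, against up to 0.82 over the settings). BCL11B (-0.25 ± 0.10, adjusted p = 0.072) did not pass, but did without N 1 (-0.36, adjusted p = 0.034) and with a replicate block (0.005), against up to 0.96. In all 73830 regions rose and 62877 fell (68731 and 70435 without bIP 2), and 3584 loci rose and 3882 fell (3795 and 3642 with total counts, 3850 and 3700 with loess scaling).

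The pan-neuronal and synapse lists rose in N, and the shared and basal radial glia, glial and cell cycle lists fell. Of 24 pan-neuronal loci, 19 rose, 4 fell and 1 did not pass (19 and 4 adjusted over the list alone), with NEUROD2 (2.93 ± 0.11, adjusted p = 9.8e-06) among the leading members. Their median was 1.00 (camera adjusted p = 8.4e-09, and adjusted p = 0.14 with an estimated correlation). Of 27 synapse and ion channel loci, 18 rose, 3 fell and 6 did not pass (18 and 3 adjusted over the list alone), with the sodium channel gene SCN3A (2.2 ± 0.15, adjusted p = 1.8e-05) among the leading members. The median was 0.65 (camera adjusted p = 4.2e-05, and adjusted p = 0.42 with an estimated correlation). Of 21 shared radial glia loci, 0 rose, 18 fell and 3 did not pass (0 and 19 adjusted over the list alone), led by HES1 (-2.37 ± 0.15, adjusted p = 1.7e-05) and by SOX2. Their median was -1.27 (camera adjusted p = 1.8e-12, and adjusted p = 0.42 with an estimated correlation). Of 18 basal radial glia loci, 1 rose, 13 fell and 4 did not pass (1 and 13 adjusted over the list alone). The median was -1.25 (camera adjusted p = 1.7e-08, and adjusted p = 0.42 with an estimated correlation). The G-protein subunit gene GNG5 (-4.16 ± 0.21, adjusted p = 1.2e-05), with 42.8 ± 2.06 CPM in aRG and 2.36 ± 0.259 in N, led the falls. The cytokine receptor gene LIFR (3.73 ± 0.41, adjusted p = 0.00014), with 1 region, rose against the list, by 4.37 without aRG 2. Of 15 glial loci, 1 rose, 9 fell and 5 did not pass (1 and 9 adjusted over the list alone), led by SOX10 (-2.51 ± 0.34, adjusted p = 0.00041), an oligodendrocyte and neural crest factor with 1 region, and ALDH1L1 (-2.22 ± 0.11, adjusted p = 1.2e-05), an astrocyte enzyme. Their median was -1.11 (camera adjusted p = 0.0014, and adjusted p = 0.42 with an estimated correlation). SOX10 fell by 3.10 without N 1. Of 24 cell cycle loci, 0 rose, 13 fell and 11 did not pass (0 and 13 adjusted over the list alone), led by the cyclin CCNA2 (-1.17 ± 0.17, adjusted p = 0.00059) and the kinase AURKB (-1.15 ± 0.20, adjusted p = 0.0015). The median was -0.29 (camera adjusted p = 0.017, and adjusted p = 0.58 with an estimated correlation). That list call ended without aRG 2 (0.051, range 0.0038 to 0.051).

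Signalling and matrix lists were also lower in N than in aRG. Of 21 BMP and TGF-beta loci, 0 rose, 18 fell and 3 did not pass (0 and 19 adjusted over the list alone), led by TGFBR2 (-3.22 ± 0.18, adjusted p = 1.2e-05) and BMPR2 (-2.67 ± 0.22, adjusted p = 3.5e-05). Their median was -0.94 (camera adjusted p = 8.4e-09, and adjusted p = 0.42 with an estimated correlation). Of 27 Wnt loci, 1 rose, 20 fell and 6 did not pass (1 and 22 adjusted over the list alone), where WNT5A (3.8 ± 0.35, adjusted p = 5.5e-05) rose and SFRP2 (-2.17 ± 0.08, adjusted p = 9.8e-06), a secreted Wnt inhibitor, fell. The median was -0.76 (camera adjusted p = 1.2e-05, and adjusted p = 0.42 with an estimated correlation). Of 15 FGF loci, 1 rose, 13 fell and 1 did not pass (1 and 14 adjusted over the list alone), led by the receptors FGFR2 (-1.73 ± 0.12, adjusted p = 1.9e-05) and FGFR3 (-1.66 ± 0.16, adjusted p = 8.1e-05). Their median was -0.69 (camera adjusted p = 3.6e-05, and adjusted p = 0.42 with an estimated correlation). Of 21 extracellular matrix and integrin loci, 4 rose, 13 fell and 4 did not pass (4 and 13 adjusted over the list alone), led by ITGB5 (-2.72 ± 0.15, adjusted p = 1.2e-05) and ITGA2 (-2.37 ± 0.14, adjusted p = 1.3e-05). The median was -0.78 (camera adjusted p = 0.00054, and adjusted p = 0.31 with an estimated correlation). Of 21 Notch loci, 4 rose, 10 fell and 7 did not pass (4 and 10 adjusted over the list alone). Their median was -0.12 (camera adjusted p = 0.023, and adjusted p = 0.42 with an estimated correlation). HES1 was followed by its relative HES5 (-1.45 ± 0.34, adjusted p = 0.0071), whose value was -1.13 without aRG 1 (adjusted p = 0.055, its highest) and -2.09 without N 1. Of 12 Hedgehog loci, 1 rose, 8 fell and 3 did not pass (2 and 9 adjusted over the list alone), where the ligand gene SHH (1.61 ± 0.11, adjusted p = 1.9e-05) rose and GLI3 (-1.34 ± 0.11, adjusted p = 3e-05) fell. The median was -0.41 (camera adjusted p = 0.041, and adjusted p = 0.42 with an estimated correlation). The Hedgehog call ended without aRG 1 (0.058), without N 2 (0.069) and with loess scaling (0.12, range 0.0084 to 0.12).

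Several lists for other fates, and the deep-layer neuron list of the cortex itself, were lower in N than in aRG. Of 17 inhibitory neuron and ganglionic eminence loci, 2 rose, 12 fell and 3 did not pass (2 and 12 adjusted over the list alone), led by the interneuron factors DLX1 (-2.43 ± 0.15, adjusted p = 1.6e-05) and LHX8 (-1.78 ± 0.20, adjusted p = 0.00016). Their median was -0.86 (camera adjusted p = 0.0011, and adjusted p = 0.42 with an estimated correlation). Of 17 non-telencephalic loci, 3 rose, 13 fell and 1 did not pass (3 and 13 adjusted over the list alone), led by the midbrain factor TAL2 (-2.38 ± 0.35, adjusted p = 0.00059) and the dorsal neural tube factor PAX7 (-1.70 ± 0.15, adjusted p = 5e-05). The median was -0.93 (camera adjusted p = 0.0098, and adjusted p = 0.42 with an estimated correlation). With a 10 kb window, TAL2 gave -1.17 and PAX7 -0.47, without a call, with adjusted p up to 0.16 and 0.074. Near the gene start TAL2 gave -1.12, also without a call. Of 18 mesenchyme and neural crest loci, 0 rose, 14 fell and 4 did not pass (1 and 14 adjusted over the list alone), where SOX10 was matched by TWIST2 (-2.55 ± 0.38, adjusted p = 0.00062). Their median was -0.99 (camera adjusted p = 0.0029, and adjusted p = 0.42 with an estimated correlation). Of 16 choroid plexus and hem loci, 2 rose, 8 fell and 6 did not pass (2 and 8 adjusted over the list alone), where RSPO3 (3.33 ± 0.26, adjusted p = 2.9e-05), a hem-derived Wnt enhancer, rose and OTX2 (-2.54 ± 0.18, adjusted p = 1.9e-05), a choroid plexus factor, fell. The median was -0.34 (camera adjusted p = 0.046, and adjusted p = 0.42 with an estimated correlation). The choroid plexus call ended without N 2 (0.073), bIP 1 (0.056) or bIP 2 (0.062) and with a 10 kb window (0.13, range 0.029 to 0.13). Of 15 deep-layer neuron loci, 3 rose, 9 fell and 3 did not pass (3 and 10 adjusted over the list alone), led by FOXP1 (-1.26 ± 0.12, adjusted p = 5.9e-05) and ETV1 (-1.22 ± 0.08, adjusted p = 1.9e-05), a pair of transcription factors of deep-layer neurons, although TBR1 of the same list rose. Their median was -0.46 (camera adjusted p = 0.01, and adjusted p = 0.42 with an estimated correlation). The deep-layer call ended with loess scaling (0.078, range 0.0001 to 0.078).

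The other 13 lists did not pass between N and aRG. Among progenitors these were apical radial glia (2 rose and 7 fell of 13, 2 and 7 adjusted over the list alone, median -0.26, camera adjusted p = 0.053, and adjusted p = 0.42 with an estimated correlation) and basal intermediate progenitor (7 rose and 6 fell of 21, 7 and 6 adjusted over the list alone, median -0.03, camera adjusted p = 0.43, and adjusted p = 0.82 with an estimated correlation). The basal intermediate progenitor mean was 0.18, against its median of -0.03. Among neurons they were upper-layer neuron (3 rose and 7 fell of 13, 3 and 7 adjusted over the list alone, median -0.38, camera adjusted p = 0.059, and adjusted p = 0.43 with an estimated correlation) and Cajal-Retzius (3 rose and 1 fell of 8, 4 and 1 adjusted over the list alone, median 0.40, camera adjusted p = 0.22, and adjusted p = 0.7 with an estimated correlation). Outside the lineage they were endothelial and immune (5 rose and 2 fell of 10, 5 and 2 adjusted over the list alone, median 0.42, camera adjusted p = 0.11, and adjusted p = 0.58 with an estimated correlation) and pluripotency (1 rose and 5 fell of 9, 1 and 5 adjusted over the list alone, median -0.52, camera adjusted p = 0.37, and adjusted p = 0.54 with an estimated correlation).

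Lists for cell shape, contact and state also stayed without a call. One was morphoregulatory and protrusion (3 rose and 8 fell of 23, 3 and 8 adjusted over the list alone, median -0.14, camera adjusted p = 0.43, and adjusted p = 0.57 with an estimated correlation), whose mean was 0.02. Others for contact were adherens and tight junction (4 rose and 6 fell of 17, 5 and 6 adjusted over the list alone, median -0.02, camera adjusted p = 0.4, and adjusted p = 0.61 with an estimated correlation) and axon guidance (6 rose and 10 fell of 24, 6 and 10 adjusted over the list alone, median -0.10, camera adjusted p = 0.29, and adjusted p = 0.63 with an estimated correlation). Hippo was also without a call (2 rose and 8 fell of 12, 2 and 8 adjusted over the list alone, median -0.30, camera adjusted p = 0.16, and adjusted p = 0.42 with an estimated correlation). For cell state there was hypoxia and glycolysis stress (3 rose and 4 fell of 12, 3 and 4 adjusted over the list alone, median -0.04, camera adjusted p = 0.85, and adjusted p = 0.88 with an estimated correlation), whose mean was 0.05. Immediate early (1 rose and 5 fell of 15, 1 and 5 adjusted over the list alone, median -0.16, camera adjusted p = 0.63, and adjusted p = 0.9 with an estimated correlation) and reference genes (1 rose and 5 fell of 14, 1 and 5 adjusted over the list alone, median -0.09, camera adjusted p = 0.8, and adjusted p = 0.83 with an estimated correlation) closed the set.

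The largest rises from aRG to N were at ADORA1 (5.15 ± 0.33, adjusted p = 1.7e-05), an adenosine receptor gene, ABCA6 (5.08 ± 0.32, adjusted p = 1.5e-05), a lipid transporter gene, and NXPE2 (4.96 ± 0.49, adjusted p = 8.2e-05), a gene of the neurexophilin family. NXPE2 rose by 4.23 without N 2. ADORA1 went from 1.61 ± 0.412 to 57.3 ± 1.62 CPM. The largest falls were at NMS (-5.11 ± 0.34, adjusted p = 1.7e-05), TECTB (-4.92 ± 0.40, adjusted p = 3.5e-05), an inner-ear matrix gene, and CCDC40 (-4.83 ± 0.40, adjusted p = 3.7e-05), a motile cilium gene. Among regions, 10:119597354-119598374 rose from 0.0616 ± 0.0317 to 9 ± 0.877 CPM (7.11 ± 0.67, adjusted p = 1.7e-06). Next were 16:15867068-15867429 (7.07 ± 0.86 from 0.021 CPM, adjusted p = 9.6e-06) and 1:220976852-220977220 (6.87 ± 0.51 from 0.0406 CPM, adjusted p = 3.4e-07). Region 19:20384265-20384845 had 2.26 ± 1.18 CPM in aRG and a count of 0 in both N libraries. It was at least 43.4-fold lower in N, against a floor of 3 counts over the population (adjusted p = 1e-05). Region 19:40887745-40888649 fell to 0.0196 CPM (-7.30 ± 0.67, adjusted p = 1.2e-06). So did 2B:58544706-58545429, 35231 bp from METAP1D, from 40.8 ± 2.83 to 0.309 ± 0.174 CPM (-7.08 ± 0.35, adjusted p = 4.3e-08). The 0.021, 0.0406 and 0.0196 CPM are under that floor, so these sizes are not measured.

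The comparison of N with bIP sets neurons against intermediate progenitors. Markers SOX2 (-1.42 ± 0.12, adjusted p = 0.00046), HOPX (-1.30 ± 0.11, adjusted p = 0.00046), EOMES (-1.04 ± 0.16, adjusted p = 0.0026), PAX6 (-0.76 ± 0.11, adjusted p = 0.0019), BCL11B (-0.58 ± 0.10, adjusted p = 0.0042) and TBR1 (-0.58 ± 0.10, adjusted p = 0.0037) fell by edgeR's quasi-likelihood test. TBR1 gave -0.23 near the gene start, with adjusted p up to 0.19. NEUROG2 (-1.17 ± 0.45, adjusted p = 0.087) did not pass, but did with DESeq2 (0.033) and a replicate block (0.038), against up to 0.32. In all 49623 regions rose and 44728 fell, and 1714 loci rose and 2410 fell. Falls outnumbered rises among regions with DESeq2 size factors (46073 and 49816 as rises and falls), loess scaling (46923 and 54310), DESeq2 (36954 and 41458) and without bIP 2 (29636 and 37315). Loci gave 929 and 1501 without bIP 2, and 1022 and 1384 without N 2. Of 21 basal intermediate progenitor loci, 1 rose, 15 fell and 5 did not pass (1 and 16 adjusted over the list alone). The median was -0.66 (camera adjusted p = 1.1e-05, and adjusted p = 0.42 with an estimated correlation). Its leading members were NEUROD4 (-1.76 ± 0.29, adjusted p = 0.0032), a proneural factor, with -2.40 without N 1, and SSTR2 (1.29 ± 0.35, adjusted p = 0.026), which rose against the list. SSTR2 lost its call without N 1 (0.89), bIP 1 (1.31) or bIP 2 (1.28), with adjusted p up to 0.11.

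The shared and basal radial glia lists and several signalling lists fell between bIP and N. Some lists that were lower in bIP than in aRG did not pass here. These were Hedgehog (1 rose and 4 fell of 12, 1 and 5 adjusted over the list alone, median -0.25, camera adjusted p = 0.4, and adjusted p = 0.67 with an estimated correlation) and extracellular matrix (5 rose and 9 fell of 21, 5 and 10 adjusted over the list alone, median -0.28, camera adjusted p = 0.21, and adjusted p = 0.42 with an estimated correlation). Others were cell cycle (0 rose and 4 fell of 24, 0 and 3 adjusted over the list alone, median -0.08, camera adjusted p = 0.27, and adjusted p = 0.79 with an estimated correlation) and Hippo (3 rose and 3 fell of 12, 3 and 3 adjusted over the list alone, median -0.02, camera adjusted p = 0.76, and adjusted p = 0.81 with an estimated correlation), the latter with an upward test and a mean of 0.12. Of 21 shared radial glia loci, 0 rose, 17 fell and 4 did not pass (0 and 20 adjusted over the list alone), where the Wnt-pathway repressor TCF7L1 (-1.44 ± 0.14, adjusted p = 0.00059) led together with SOX2 at -1.42. Their median was -0.64 (camera adjusted p = 2.8e-10, and adjusted p = 0.42 with an estimated correlation). Of 18 basal radial glia loci, 1 rose, 12 fell and 5 did not pass (1 and 12 adjusted over the list alone), with LIFR (2.88 ± 0.39, adjusted p = 0.0015) against the list and GNG5 (-2.60 ± 0.22, adjusted p = 0.00046) along it. The median was -0.60 (camera adjusted p = 1.1e-05, and adjusted p = 0.42 with an estimated correlation). Of 27 Wnt loci, 0 rose, 14 fell and 13 did not pass (1 and 20 adjusted over the list alone), where TCF7L1 was followed by SFRP2 (-1.25 ± 0.08, adjusted p = 0.00043). Their median was -0.47 (camera adjusted p = 2.2e-05, and adjusted p = 0.42 with an estimated correlation). Of 21 BMP and TGF-beta loci, 0 rose, 13 fell and 8 did not pass (0 and 13 adjusted over the list alone), led by TGFBR2 (-1.96 ± 0.18, adjusted p = 0.00054) and BMPR2 (-1.21 ± 0.22, adjusted p = 0.0051). The median was -0.41 (camera adjusted p = 9.8e-06, and adjusted p = 0.42 with an estimated correlation). Of 21 Notch loci, 1 rose, 14 fell and 6 did not pass (1 and 15 adjusted over the list alone), led by HES1 (-1.25 ± 0.15, adjusted p = 0.0011) and the ligand gene DLL3 (-1.21 ± 0.14, adjusted p = 0.001). Their median was -0.39 (camera adjusted p = 5e-04, and adjusted p = 0.42 with an estimated correlation). Of 15 FGF loci, 1 rose, 7 fell and 7 did not pass (1 and 9 adjusted over the list alone), led by FGFR3 (-1 ± 0.16, adjusted p = 0.0032) and FGFR2 (-0.91 ± 0.12, adjusted p = 0.0013). The median was -0.24 (camera adjusted p = 0.0097, and adjusted p = 0.47 with an estimated correlation). The FGF call ended with loess scaling (0.1, range 0.0031 to 0.1), and that of FGFR3 with a 10 kb window (-0.43) and near the gene start (-0.30), with adjusted p up to 0.24. Of 15 glial loci, 0 rose, 5 fell and 10 did not pass (0 and 5 adjusted over the list alone), led by SOX10 (-2.10 ± 0.34, adjusted p = 0.0032), which gave -2.69 without N 1, and ALDH1L1 (-1.28 ± 0.11, adjusted p = 0.00046). Their median was -0.46 (camera adjusted p = 0.014, and adjusted p = 0.42 with an estimated correlation).

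Neuronal lists did not move together between bIP and N. Of 24 pan-neuronal loci, 6 rose, 3 fell and 15 did not pass (8 and 4 adjusted over the list alone). The median was 0.17 (camera adjusted p = 0.075, and adjusted p = 0.42 with an estimated correlation). Of 27 synapse and ion channel loci, 10 rose, 3 fell and 14 did not pass (11 and 4 adjusted over the list alone), led by the GABA receptor gene GABRA2 (1.99 ± 0.31, adjusted p = 0.0026) and by GRIK2 (-1.78 ± 0.32, adjusted p = 0.0046), which fell after its rise in bIP. Their median was 0.15 (camera adjusted p = 0.016, and adjusted p = 0.42 with an estimated correlation). The synapse call ended without N 1 (0.051) and without bIP 2 (0.074, range 0.0029 to 0.074). Of 15 deep-layer loci, 1 rose, 10 fell and 4 did not pass (1 and 10 adjusted over the list alone), with LDB2 (0.97 ± 0.13, adjusted p = 0.0015), a transcriptional cofactor of subcerebral neurons, and ETV1 (-0.82 ± 0.08, adjusted p = 0.00066). The median was -0.40 (camera adjusted p = 0.0033, and adjusted p = 0.42 with an estimated correlation). The list call ended with loess scaling (0.089, range 1.6e-05 to 0.089), and that of LDB2 with a 10 kb window (0.23) and near the gene start (0.24), with adjusted p up to 0.27. Of 13 upper-layer loci, 2 rose, 6 fell and 5 did not pass (2 and 6 adjusted over the list alone), led by MEF2C (-1.46 ± 0.31, adjusted p = 0.0091) and POU3F2 (-0.83 ± 0.12, adjusted p = 0.0019), transcription factors of later-born neurons. Their median was -0.32 (camera adjusted p = 0.048, and adjusted p = 0.42 with an estimated correlation). That call ended without N 1 (0.12), N 2 (0.054) or bIP 2 (0.063), with a 10 kb window (0.057) and with loess scaling (0.088, range 0.019 to 0.12). MEF2C gave -0.64 with a 10 kb window and -1.02 near the gene start, with adjusted p up to 0.42. Of 17 inhibitory loci, 1 rose, 14 fell and 2 did not pass (1 and 14 adjusted over the list alone), led by DLX1 (-1.29 ± 0.16, adjusted p = 0.0011) and LHX8 (-1.28 ± 0.20, adjusted p = 0.0029). The median was -0.61 (camera adjusted p = 0.00019, and adjusted p = 0.42 with an estimated correlation).

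Remaining calls between bIP and N were for fates outside the cortex. Of 17 non-telencephalic loci, 0 rose, 8 fell and 9 did not pass (1 and 11 adjusted over the list alone), led by TAL2 (-1.97 ± 0.36, adjusted p = 0.0049) and the midbrain and hindbrain factor EN2 (-1.37 ± 0.28, adjusted p = 0.0084), which gave -1.17 without N 2 (adjusted p = 0.055, its highest). Their median was -0.52 (camera adjusted p = 0.007, and adjusted p = 0.42 with an estimated correlation). Of 18 mesenchyme and neural crest loci, 1 rose, 8 fell and 9 did not pass (1 and 10 adjusted over the list alone). The median was -0.54 (camera adjusted p = 0.021, and adjusted p = 0.42 with an estimated correlation). That call ended without bIP 1 (0.056, range 0.011 to 0.056). Besides SOX10 it was led by TWIST2 (-1.41 ± 0.40, adjusted p = 0.03), with -1.15 without N 2 and -1.12 without bIP 1, neither called (adjusted p up to 0.14). The largest rises were at NXPE2 (3.76 ± 0.45, adjusted p = 0.001), which gave 3.03 without N 2, NPY2R (3.27 ± 0.25, adjusted p = 0.00046), a neuropeptide Y receptor gene, and TMEM59 (3.12 ± 0.25, adjusted p = 0.00046), a Golgi membrane protein gene. NPY2R went from 5.84 ± 1.42 to 56.4 ± 1.84 CPM. The largest falls were at HSD17B2 (-3.12 ± 0.15, adjusted p = 8.9e-05), a steroid-metabolising enzyme gene, SPATA3 (-3.03 ± 0.98, adjusted p = 0.048), a testis gene, and TXNDC2 (-3.02 ± 0.32, adjusted p = 0.00072), a sperm thioredoxin gene. HSD17B2 went from 47.5 ± 5.16 to 5.45 ± 0.281 CPM. The SPATA3 fall rested on uneven libraries (10.3 ± 9.72 CPM in bIP) and gave -2.60 without N 1, -3.54 without N 2, -3.77 without bIP 1 and -1.45 without bIP 2, called only without bIP 1 among these (adjusted p up to 0.36).

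Single regions moved strongly between bIP and N too. Rises were led by 14:18084033-18084596 (log2 fold change 5.43 ± 0.81, adjusted p = 0.00022), 2A:63409931-63410885 (5.32 ± 0.6, adjusted p = 5.2e-05) and 13:45170243-45171037 (4.35 ± 0.62, adjusted p = 0.00017). Region 19:20384265-20384845, with 0.577 ± 0.11 CPM in bIP and a count of 0 in N, was at least 11.1-fold lower in N (adjusted p = 0.00087). Falls followed at 18:44976993-44977879 (-5.60 ± 0.53, adjusted p = 2.3e-05) and 4:165737737-165738799, from 28.9 ± 12.2 to 0.729 ± 0.198 CPM (-5.27 ± 0.29, adjusted p = 1.8e-06).

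Between bIP and bRG, 44477 regions rose and 40473 fell, and 2093 loci rose and 1886 fell (1995 and 2069 with total counts, 801 and 857 near gene starts). Without bIP 1, 25002 regions fell. The locus total of 3979 became 2348 without bIP 1, 2416 without bRG 1 and 2513 without bRG 2. Markers that rose were TBR1 (1.48 ± 0.10, adjusted p = 0.00011), EOMES (0.88 ± 0.16, adjusted p = 0.0044) and BCL11B (0.36 ± 0.10, adjusted p = 0.03), while SOX2 (-0.86 ± 0.11, adjusted p = 0.00086), HOPX (-0.62 ± 0.10, adjusted p = 0.0028) and PAX6 (-0.58 ± 0.10, adjusted p = 0.0042) fell. BCL11B lost its call without bIP 1 (0.31), bIP 2 (0.41) or bRG 2 (0.27) and near the gene start (0.24), with adjusted p up to 0.18, and PAX6 lost it near the gene start (-0.29, up to 0.17). NEUROG2 (-1.19 ± 0.41, adjusted p = 0.062) did not pass, but did without aRG 1 (-1.19), aRG 2 (-1.19) or bRG 1 (-1.55), with DESeq2 (-1.2) and with a replicate block (-1.16), against up to 0.34. Regions that led the changes were 17:34319067-34319717 (5.26 ± 0.46, adjusted p = 1e-05), 20:60309165-60309820 (4.88 ± 0.51, adjusted p = 2.5e-05) and 7:66356558-66356880 (4.85 ± 0.65, adjusted p = 0.00011) upward. Downward they were 17:22983192-22983588 (-3.60 ± 0.68, adjusted p = 0.001), 11:67227968-67228506 (-3.56 ± 0.51, adjusted p = 0.00017) and 12:59652087-59652934 (-3.53 ± 0.42, adjusted p = 5e-05).

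Between N and bRG, 74338 regions rose and 60232 fell, and 3555 loci rose and 3709 fell (3717 and 3546 with total counts, 3771 and 3661 with loess scaling). Markers SOX2 (-2.27 ± 0.12, adjusted p = 1.5e-05), NEUROG2 (-2.36 ± 0.44, adjusted p = 0.0023), HOPX (-1.92 ± 0.11, adjusted p = 1.5e-05) and PAX6 (-1.34 ± 0.11, adjusted p = 3.7e-05) fell and TBR1 (0.90 ± 0.10, adjusted p = 0.00017) rose, by edgeR's quasi-likelihood test. EOMES (-0.15 ± 0.16, adjusted p = 0.45) and BCL11B (-0.23 ± 0.10, adjusted p = 0.095) did not pass, but did without N 1 (-0.46 and -0.34), and BCL11B also with a replicate block (adjusted p = 0.0079), against up to 0.97 and 0.75. Regions 7:121467386-121467877 (5.81 ± 0.57, adjusted p = 2.6e-06), 2B:7013808-7014166 (5.39 ± 0.55, adjusted p = 3.7e-06) and 5:100810495-100811104 (5.39 ± 0.44, adjusted p = 9e-07) led the rises. The falls were at 19:20384265-20384845, at least 46.5-fold lower in N (adjusted p = 9.7e-06), and at the regions on 19 and 2B that also fell against aRG (-7.16 ± 0.68 with adjusted p = 1.8e-06, and -6.98 ± 0.35 with adjusted p = 6.4e-08).

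Many regions moved in the same direction at both steps, from aRG to bIP and from bIP to N. Regions that rose at both steps numbered 16994, where 12174 would be expected if the 2 sets of calls were independent. Regions that fell at both steps numbered 19549, against 10127. Regions higher in bIP than in both neighbours numbered 11546, against 10973, and regions lower than in both 1568, against 11236. Simulated unchanged data had 0 calls from bIP to N, so could show none. Both steps share the bIP libraries, so calls are not independent, and bIP error favours opposite directions. The count of stepwise rises was 10416 without aRG 1, 10034 without bIP 1 and 9383 without bIP 2. The count lower in bIP than in both was 825 without aRG 1, 851 without aRG 2, 905 without bIP 1 and 665 without bIP 2. It was 955 with total counts, 869 with DESeq2 and 2735 with a replicate block.

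Regions far from gene starts changed more often than regions near them. Between N and aRG, 56.1% of regions within 1 kb of the closest gene start changed, 67.1% at 1 to 10 kb, 70.6% at 10 to 50 kb and 73.9% beyond 50 kb. The median size of the log2 fold change was 0.53 within 1 kb and 1.96 beyond 50 kb. Between bIP and aRG the share went from 42.4% to 49.5%, and between N and bIP from 28.2% to 53.2%. Over the alternatives these shares lay, for N against aRG, between 45.3 and 67% within 1 kb and between 63.8 and 77.2% beyond 50 kb. For bIP against aRG they lay between 24.9 and 52.4%, and between 33.8 and 57.4%. The percent of regions changed within 1 kb was 25.1 without aRG 1, 28 without aRG 2, 24.9 without bIP 1 and 27 with DESeq2 for bIP vs aRG. For N against bIP the ranges were 17.4 (without N 2) to 42.2% within 1 kb and 35.9 to 59.9% beyond 50 kb. Within 1 kb, 3569 regions rose and 8502 fell between aRG and N under TMM scaling. The split was 3226 and 10142 with DESeq2 size factors, 4190 and 6976 with total counts and 3060 and 11500 without bIP 2, and it turned to 8811 and 5076 with loess scaling. Between aRG and bIP it was 2302 and 6827, then 2806 and 3521 with total counts, 1993 and 3805 with DESeq2, and 3786 and 3056 with loess scaling. It was 1680 and 3759 without aRG 1, 1718 and 4352 without aRG 2, and 1632 and 3767 without bIP 1. Between bIP and N it was 2449 and 3620, then 1094 and 3480 without bIP 2, 1615 and 2158 without N 2, and 5653 and 3414 with loess scaling.

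**Figure D4:**
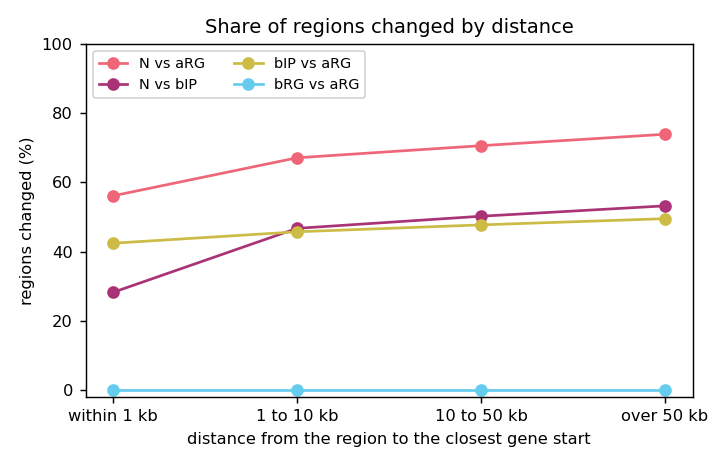
Percent of tested regions with an adjusted p under 0.05 in 4 comparisons, by distance from the region to the closest gene start. In N against aRG the share goes from 56.1% within 1 kb to 73.9% beyond 50 kb, and it is 0 at every distance in bRG against aRG.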

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

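The total-count and loess scalings for gene loci and gene lists, and all alternatives for the split near gene starts, the shares by distance and the patterns across bIP, were chosen after seeing the data, and the others were planned. Corrections for GC content, alone and with the replicate block, and the alternatives for motif shares were planned but not run, because the genome sequence was not at hand. Where a library was left out, the lone library of its population was assumed to vary like the other groups.

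For changed regions, leaving out 1 library at a time gave 132519 to 143609 regions changed among the 4 populations, 119028 to 139166 for N against aRG, 115439 to 136425 for N against bRG, and 66951 to 90847 for N against bIP. It gave 64561 to 97536 for bIP against aRG, 56230 to 88925 for bIP against bRG, and 0 to 0 for bRG against aRG. Over the other settings the ranges were 129913 to 156655 among the populations, 122503 to 144769 for N against aRG, 119507 to 143248 for N against bRG, 78412 to 109407 for N against bIP, 77850 to 106317 for bIP against aRG and 71653 to 98176 for bIP against bRG. For bRG against aRG every setting, edgeR or DESeq2, gave 0 regions and 0 loci. With 200 changes simulated and fitted without library numbers, 3% of 2-fold changes at regions and 70.1% at loci were recovered. Neither pairing nor a block was simulated, so these rates do not measure power here.

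For gene loci, leaving out 1 library gave 5591 to 7380 for N against aRG, 5393 to 7246 for N against bRG, 2406 to 4246 for N against bIP, 2500 to 4753 for bIP against aRG, 2348 to 4330 for bIP against bRG and 0 to 0 for bRG against aRG. Fewer libraries leave fewer degrees of freedom, which can lower such counts. With only the regions near gene starts, 1917 loci changed for bIP against aRG, 1658 for bIP against bRG and 2067 for N against bIP, and fewer loci and counts were tested there.

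With a replicate block, which takes library numbers 1 and 2 as a term, all counts rose except those of bRG against aRG, which stayed at 0. Regions numbered 156655 among the populations, 144769 for N against aRG, 143248 for N against bRG, 109407 for N against bIP, 106317 for bIP against aRG and 98176 for bIP against bRG. Loci numbered 8901, 8821, 6088, 6010 and 5613 for the same 5 pairs. Libraries of the same number deviated from their population means together, with correlations across regions of 0.31 for aRG and bRG, 0.28 for bRG and bIP, 0.24 for bIP and N, 0.2 for bRG and N, and 0.12 for aRG with bIP and with N. The third principal component (3.3% of variance) separated the numbers. Library numbers are consecutive within each number, and no batch is stated in the labels. Each number holds 1 library per population, so no value within a number can be tested.

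Of the gene lists, 83 tests passed with the preset correlation and 0 with an estimated correlation, which comes from 8 libraries. Leaving out 1 library gave 75 to 89. Of the 83, the same direction and call were kept by 82 with the block, 83 with DESeq2 size factors, 83 with total counts, 74 with loess scaling and 74 with a 10 kb window. Without 1 library, between 75 (without aRG 1 or bIP 2) and 80 (without bIP 1) kept both. The direction reversed for axon guidance in bRG against aRG without aRG 1 (adjusted p = 0.98, over a range of 0.0015 to 0.98) and for cell cycle in bRG against aRG without bRG 1 (0.53, over 1.4e-07 to 0.63). The cause was not tested.

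Of the 145 results kept for gene loci, none that was called reversed, while uncalled values near 0 changed sign (NEUROG2 in bRG against aRG lay between -0.34 and 0.68). All 145 kept their side of the threshold with DESeq2 size factors, total counts, loess scaling and no filter. Calls were lost by 8 of 126 with a 10 kb window, 9 of 106 near gene starts and 1 with DESeq2. Some also ended without 1 library. FLT1, TPCN1, NPY2R, RSPO3, LIFR, GNG5, BMPR2, SSTR2, GRIK2, TWIST2 and SPATA3 were tested in neither window. Where calls were kept, 11 values moved over 1.5-fold with a 10 kb window and 16 near gene starts. For N against aRG these included FGFR3 (-1.66, then -0.64 and -0.5), ITGA2 (-2.37, then -1.19 and -1.14) and DLX1 (-2.43, then -1.49 and -1.45). ITGB5 went from -2.72 to -1.26 near gene starts, ADORA1 from 5.15 to 3.46 with a 10 kb window, and SHH from 1.61 to 1.01 and 2.78. Over all 419 loci of the naming rule, 9 of 372 reversed with a 10 kb window and 15 of 281 near gene starts. The 30 results for 25 regions kept direction and call in all settings run.

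Among changed regions near gene starts, falls became a minority under loess scaling. Their percent went from 70.4 to 36.6 for N against aRG, 59.6 to 37.7 for N against bIP and 62.8 to 35.1 for N against bRG. It went from 74.8 to 44.7 for bIP against aRG and 62.4 to 44.0 for bIP against bRG.

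Overlaps of the peak lists were lower by construction when 50% of both intervals had to be shared. For aRG they became 89.4% in bRG, 62.4% in bIP and 45.2% in N, and for N 45% in aRG and 62.5% in bIP. With the most significant part of each list they were 95.9, 64.9, 48.6, 48.4 and 65.4% in the same order, and the cause was not tested.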

Other observations

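The tests in this part were fixed in writing before their results were seen, except where stated, but after the patterns themselves had been noticed. The bRG libraries lay between aRG and N on the leading principal component. Regions specific to N were chosen in 1 library of each population and measured in the other. Their median log2 ratio of bRG to aRG was 0.26 over 26942 regions and 0.29 over 38756, while radial glia-specific regions gave -0.06 and -0.08. The N-specific regions implied that 1.8% and 3.2% of the bRG signal was of neuronal type, and bIP-specific regions that 1.1% and -3.3% was of bIP type. A share above 0 from N-specific regions follows from the order on the component, so it does not test whether the bRG sort held cells with neuronal chromatin. That and partly neuronal chromatin within bRG cells stay open. Weak regions similar across populations, chosen for a like signal in radial glia, gave 0.04 and -0.03, at least 0.22 log2 less than N-specific regions. They were stronger as measured, with aRG medians of 0.5 and 0.7 CPM against 0.38 and 0.35, so the log2 ratios are not matched. In CPM, compared after these values were seen, their medians went from 0.5 to 0.51 and from 0.7 to 0.67, and those of N-specific regions from 0.38 to 0.48 and from 0.35 to 0.44. This argues against an even background added in bRG, which would raise both alike, and an uneven one stays open.

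Library bIP 2 lay nearer to radial glia than bIP 1 on the same component. If the second sort held more radial glia, bIP-specific and N-specific regions would both be lower in it. The median log2 ratio of bIP 2 to bIP 1 was 0.05 in 5588 bIP-specific regions, -0.31 in 34020 N-specific regions and 0.42 in 25330 radial glia-specific regions. The value of 0.05 argues against added radial glia alone. A mixture that also held fewer neuron-like cells may account for the difference and was not tested.

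More regions near gene starts fell than rose between aRG and N under TMM scaling, with a ratio of 2.38. The ratio was 3.14 with DESeq2 size factors, 1.66 with total counts and 0.58 with loess scaling. Loess alone turned the direction, but removes shifts shared by regions of like abundance, so cannot decide the cause. No biological explanation was tested.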
